A study of Rattus norvegicus with 3 samples.

How the data were processed

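The labels describe extracellular vesicles of primary rat astrocytes, with 1 library each from untreated, IL-1α/TNF-α/C1q-treated and IL-4/C1q-treated cells. Per the labels' protocols, libraries were made from EV RNA and sequenced on an Illumina instrument. Another sentence of the same protocol speaks of RNA taken from harvested astrocytes, so the labels leave some doubt about the RNA source. The aligner, the counting tool, the miRNA database version and the genome build are not given in the sources used here, so no genomic coordinates are printed.

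Each deposited file held 1480 rows in the same order, with an estimated count column that the file headers call raw and a scaled signal column that they call normalized. The deposited estimated counts were not all whole, with a tolerance of 1e-06: 237, 140 and 151 rows of the untreated, IL-1α/TNF-α/C1q and IL-4/C1q libraries held fractions, and rows sharing a name held equal parts, as when reads that match several rows are divided among them. The deposited signal was the count times a constant per library, 1.25, 0.684 and 1.14; how the authors set it is not stated, and the signal was used here only as an alternative scaling. Row names carried species prefixes, isoform suffixes and substitution tags, per the file headers and rows. Of the 1480 rows, 548 were rat-named, 179 bovine-named and 372 were predicted candidates with no miRNA name. Species prefixes show which database entry a row was assigned to, and do not by themselves show which organism the RNA came from.

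Predicted candidates, 0.066%, 0.036% and 0.034% of the counts, were left out of the totals. Rows of a mature name were summed to 919 miRNAs, 504 of them rat-named; substitution-tagged rows were kept apart where the plain name also had a row. The plan made before the data were examined was to keep the highest row of a name, on the assumption that whole reads were repeated in several rows. The fractional counts showed that reads were divided instead, so the sum was taken before any comparison was computed, and the highest row became the alternative. Counts that different names share, such as those of miR-1-3p and miR-1b, remain divided and are uncertain.

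CPM is a count divided by the miRNA-named counts of its library, on a scale where each library sums to 1e6. A ratio is a ratio of such shares, with an exact conditional binomial 95% interval; estimated counts were rounded to whole numbers for intervals, scaling factors and the exact test. The size rule, fixed before the data were examined, asks for a ratio of at least 2-fold, an interval excluding 1 and at least 50 counts in the higher library. PCR copies are not independent molecules, so intervals and floors cover counting error only. Against a count of 0, a bound was computed against a floor of 5 counts in that library. This floor was set after the values were seen, because whole-number rows mostly start at 5: of whole values not repeated in another row, 0 of 601, 2 of 608 and 3 of 592 lay under 5, while among all whole values above 0 it was 37 of 1007, 22 of 822 and 13 of 709. Such bounds are therefore approximate.

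The 22 lists were also fixed beforehand: NF-kB and IL-1/TNF responsive, IL-4 or alternative activation, astrocyte, neuron, microglia and leukocyte, oligodendrocyte, endothelial, mesenchymal, epithelial, muscle, erythrocyte and serum, let-7, miR-17-92, miR-23-27-24, miR-29, miR-30, miR-181, miR-221 with miR-222, miR-34 with miR-449, Dlk1-Dio3, hypoxia and ischemia, and leukocyte adhesion. Of 224 listed names 210 were in the files. A list's median log2 ratio (CPM + 1) was placed as a percentile among 10000 random lists of the same size matched on mean expression in 10 bins, over 754 miRNAs with at least 10 counts in all libraries together. It was called apart under 2.5 or over 97.5, with at least 3 members. Lists share members: all 12 of the leukocyte adhesion list and 7 of 12 of the IL-4 list are in other lists, and 1 mesenchymal miRNA is in the astrocyte list.

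The named miRNAs follow a rule fixed beforehand: per comparison the 12 highest and 12 lowest ratios past the size rule with at least 200 counts, the 8 most abundant of each library, and up to 4 members per list by mean CPM. Exceptions are said to be chosen after their values were seen; the epithelial, erythroid, mesenchymal and Dlk1-Dio3 members named outside the rule, among them miR-10a-5p, miR-486, miR-182 and miR-183-5p, were too.

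Alternatives were edgeR 4.0.16 TMM factors, DESeq2 1.42.0 size factors, totals without the most abundant miRNA, other count and fold minimums, and an edgeR exact test with an assumed dispersion of 0.1. Alternatives added after the data were seen were the authors' constants, predicted candidates included, rat-named rows only, and leaving out bovine-named rows with the epithelial and the erythrocyte and serum lists. The median log2 ratio of all tested miRNAs was −0.07, −0.17 and −0.06 in the 3 comparisons. DESeq2 size factors shifted every log2 ratio by 0.12, 0.18 and 0.06, TMM factors by 0.07, 0.12 and 0.05, and the authors' constants by 0.09, 0.17 and 0.08. The computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9 and R 4.3.3.

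The steps were tested on simulated data. For the size rule 200 of 919 miRNAs were changed. In each comparison 100% of the 3-, 4- and 8-fold changes passed the size rule, and 0 of 50 changed 1.5-fold and 0 of 719 unchanged miRNAs did. The changed miRNAs were drawn from those with at least 100 expected counts in the smaller library, so rarer ones were not covered. Many of the 719 unchanged ones had fewer than 50 counts and could not pass. The list call was tried on separate simulated libraries, in which only the members of a raised list differed. It was not tried where many other miRNAs differ. Of 400 unchanged lists 17, 15 and 17 were called apart. This number of lists was set after a smaller run, in which a larger share had been called apart. Simulated libraries varied by counting error alone, so these values say nothing about variation between cultures.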

Results

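Per the labels, small RNA was sequenced from extracellular vesicles (EVs, membrane particles that cells release into their medium) of primary rat astrocytes. A sentence of the protocol speaks of RNA from harvested astrocytes, so the EV source is in some doubt. The astrocytes were left untreated, or were treated from day 6 for 24 h with IL-1α, TNF-α and complement C1q, a mixture used to drive astrocytes into an inflammatory reactive state, or with IL-4 and C1q, which replaces the inflammatory cytokines with one linked to alternative activation. There was 1 library for each of the 3 conditions, all from the same batch per the labels. The files held 6318839 miRNA counts (rounded) for the untreated library, 12327301 for the IL-1α/TNF-α/C1q library and 7779718 for the IL-4/C1q library. Because no condition had a replicate, differences are given as ratios between libraries with 95% intervals that cover counting error only; there is no replicate check, and a ratio compares libraries rather than conditions. CPM stands for a count scaled to a library total of 1e6. miRNAs are rat-named unless a prefix of another species is given.

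The counts were dominated by the same few miRNAs in all 3 libraries. miR-21-5p, an abundant glial miRNA, took 35.8% of the counts in the untreated library (Clopper-Pearson 95% interval 35.7 to 35.8%), 36.5% in the IL-1α/TNF-α/C1q library and 38.7% in the IL-4/C1q library. miR-9a-5p, a neural lineage miRNA, was second in the untreated library with 4.46%, and held 3.22% and 3.39% of the treated libraries. miR-125b-5p held 4.02%, 3.43% and 3.42%, and miR-99a-5p 3.44%, 3.02% and 2.75%. miR-30a-5p, let-7c-5p and miR-29a-3p were among the 8 most abundant of every library, with 3.50%, 2.89% and 2.41% of the untreated counts. miR-143-3p, known from smooth muscle and other mesenchymal cells, ranked 17 in the untreated library with 1.21%, 4 after IL-1α/TNF-α/C1q with 3.06% and 2 after IL-4/C1q with 4.90%. Rat-named miRNAs made up 93.8%, 94.3% and 94.4% of the counts. Bovine-named rows held 4396 CPM in the untreated library against 595 and 751 CPM in the IL-1α/TNF-α/C1q and IL-4/C1q libraries. The largest part in each was bta-miR-1246, with 15956.5, 3971 and 3025 counts. The human-named hsa-miR-1246 moved alike, with 12230, 2851 and 2534 counts. Both were named after their values were seen.

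The first comparison asked how the sequenced miRNAs of astrocytes given the inflammatory mixture differed from those of untreated astrocytes. The largest differences were lower shares of epithelial and erythroid miRNAs than in the untreated library. With 1 untreated library, a loss after treatment and an excess in that library cannot be told apart. miR-200c-3p, which maintains the epithelial state, was 359-fold lower in the IL-1α/TNF-α/C1q library (95% interval 269.6 to 489), at 47 counts against 8646. miR-451-5p, an erythroid miRNA, was 272-fold lower (198 to 384). On the other side, miRNAs of the Dlk1-Dio3 imprinted cluster and the mesenchymal miR-199a and miR-143 were 2.29- to 3.85-fold higher in examples such as miR-127-3p, miR-143-3p, miR-199a-3p and miR-541-5p. Of 514 miRNAs with at least 50 counts in the higher library, 177 differed at least 2-fold with an interval excluding 1, 68 higher and 109 lower. The split moved with the setting: it was 86 higher and 104 lower with DESeq2 size factors, 6 and 77 at a 4-fold minimum, and 30 and 97 in an edgeR exact test with an assumed dispersion of 0.1, a value the data could not estimate. Of the 109 lower ones 46 were rat-named and 25 bovine-named. Counted in rat-named rows alone, 100 miRNAs passed, 54 of them higher.

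All 8 epithelial-list members that had enough counts were lower after IL-1α/TNF-α/C1q, among 10 measured. The list median log2 ratio was −3.92, and 0% of 10000 expression-matched random lists lay lower. Within it miR-200b-3p was 175-fold lower (138 to 226), miR-200a-3p 129-fold lower (95.8 to 179) and miR-205 24.98-fold lower (21.5 to 29.2). miR-203a-3p was 3.24-fold lower (3.01 to 3.50). miR-141-3p had 273 counts in the untreated library and 0 in both treated libraries, at least 107-fold lower against a floor of 5 counts. The rat-named miR-429 row had 0, 5 and 0 counts in the untreated, IL-1α/TNF-α/C1q and IL-4/C1q libraries, while the marmoset-named cja-miR-429 had 308, 0 and 0. hsa-miR-934, with 351 untreated counts, was also at 0 in both treated libraries, at least 137-fold lower after IL-1α/TNF-α/C1q. In the erythrocyte and serum list 5 of 9 members were lower and none was higher, with a median of −2.45 at percentile 0.03. miR-144-5p, transcribed with miR-451, was 71.5-fold lower (32.3 to 197). miR-122-5p, a liver miRNA abundant in serum, had 11049 counts against 44888 in the untreated library, 7.93-fold lower as a share (7.76 to 8.09). miR-92a-3p and miR-191a-5p of the same list had ratios within 2-fold, with log2 values of 0.02 and 0.70. The bovine-named miRNAs with no rat-named row of the same name went the same way: 21 of 24 were lower, with a median 10.1-fold. Of 10 primate-named miRNAs with no rat-named row, 6 were lower and 0 higher, with a median 5.61-fold lower. The fall was thus not particular to bovine names. Both sets rest on names alone and may hold relatives of rat miRNAs that are named differently.

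Among the lists that were higher, 5 of 9 fibroblast and mesenchymal miRNAs were higher and 2 lower, with a median log2 ratio of 1.06 at percentile 99.9. miR-143-3p was 2.52-fold higher (2.499 to 2.54), miR-199a-3p 3.003-fold (2.96 to 3.05), and miR-199a-5p had a log2 ratio of 1.58. mmu-miR-199b-5p, which is not in the list, had 1.49. The lower members were miR-10a-5p and miR-10b-5p, by 12.3-fold (11.4 to 13.4) and 9.19-fold (8.85 to 9.53). Of 42 measured Dlk1-Dio3 miRNAs, 15 were higher and 1 lower, with a median of 0.79 above every random list. miR-541-5p was 3.85-fold higher (3.41 to 4.35), miR-381-3p 2.81-fold (2.62 to 3.01) and miR-127-3p 2.29-fold (2.20 to 2.38). The lower member was miR-369-3p, by 3.46-fold (3.25 to 3.68), named after its values were seen. The miR-17-92 cluster and its paralogs, a group known for promoting proliferation, had 5 of 15 members higher and none lower, with a median of 0.60 at percentile 99.1. miR-20a-5p was 3.23-fold higher (3.17 to 3.298), miR-93-5p 2.86-fold (2.80 to 2.93) and miR-18a-5p 3.50-fold (2.45 to 5.14). The most abundant members, miR-25-3p and miR-92a-3p, had log2 ratios of 0.76 and 0.02, short of 2-fold. miR-490-3p, miR-329-5p, miR-540-3p and mir-6329-p3, in none of these lists, had log2 ratios of 1.85, 1.82, 1.75 and 1.93. By name, miR-329-5p is the other arm of miR-329-3p, which is in the Dlk1-Dio3 list and was also higher. Genomic positions were not examined, so absence from that list does not place an miRNA outside the cluster.

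The miRNAs listed beforehand as NF-kB and IL-1/TNF responsive did not stand apart as a group after IL-1α/TNF-α/C1q: 1 of 15 was higher and 2 were lower, with a median log2 ratio of 0.12 at percentile 69.6. Chosen after their values were seen, the ones past the rule were miR-132-5p, 2.73-fold higher (1.70 to 4.59), and miR-147 and miR-31a-3p, 2.45-fold (1.82 to 3.32) and 2.82-fold (1.83 to 4.39) lower. miR-155-5p, induced by inflammatory signals in many cells, was 1.598-fold higher (1.52 to 1.68), short of 2-fold. miR-146a-5p, a feedback inhibitor of NF-kB signalling that was also chosen after its values were seen, was 1.69-fold lower (1.60 to 1.78). The IL-4 or alternative macrophage activation list had a median of −0.72 at percentile 2.17, with 2 of 12 members lower, miR-124-3p and mmu-miR-223-3p. That call was lost with a pseudocount of 10 CPM (percentile 24.9), a background of at least 100 counts (8.11) and 5 expression bins (2.61).

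**Figure D1:**
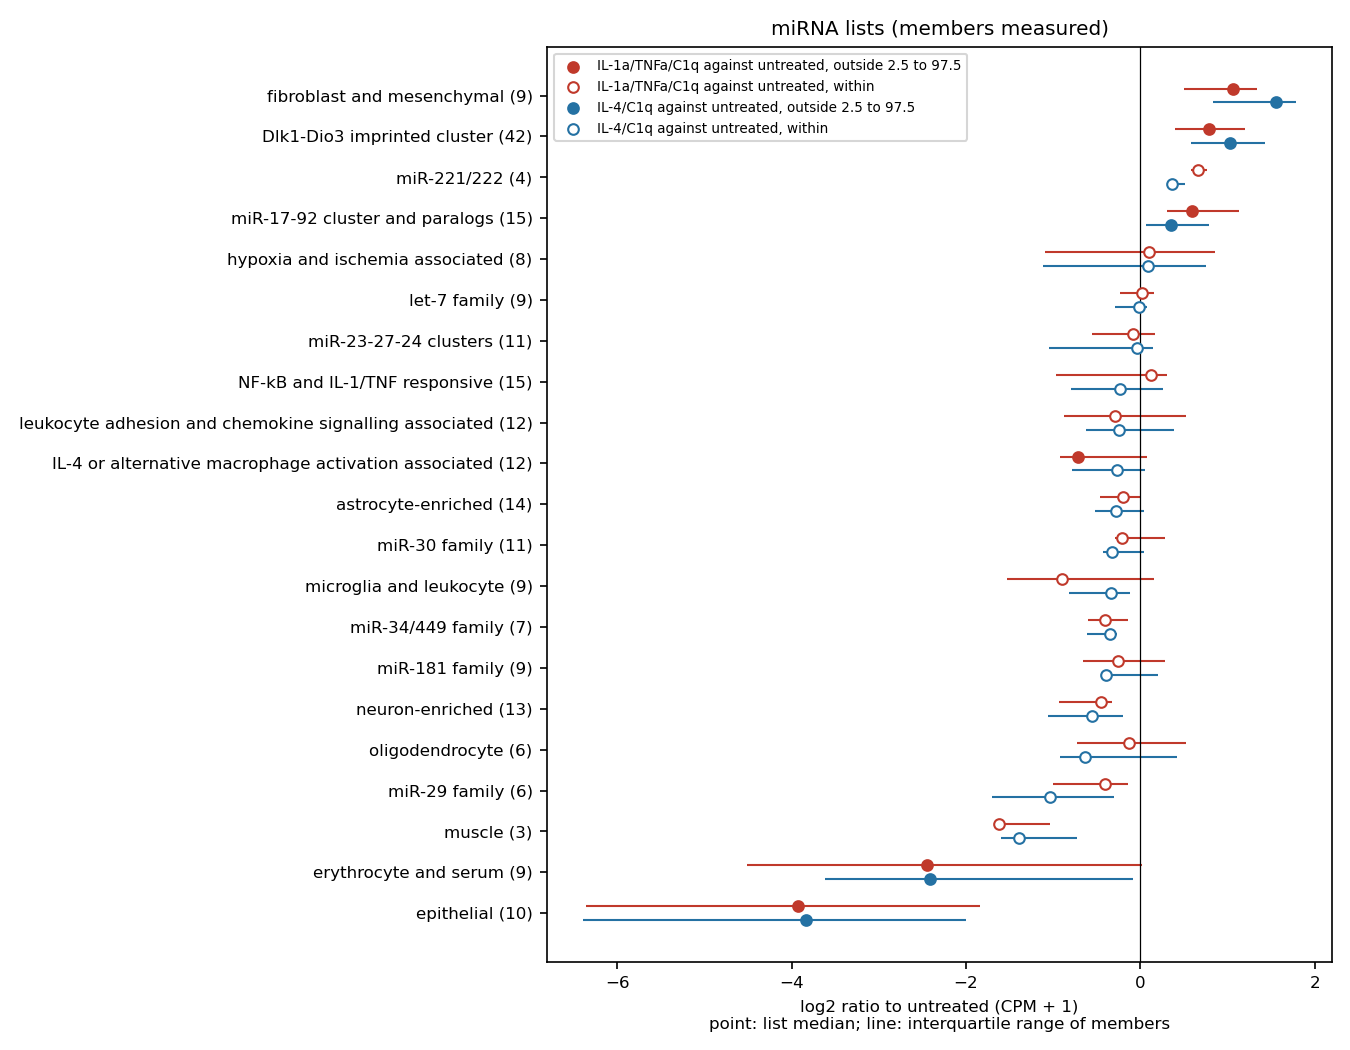
List median log2 ratio to the untreated library (x axis, CPM + 1) for each miRNA list with at least 3 measured members (y axis, number measured in brackets), for the IL-1α/TNF-α/C1q library in red and the IL-4/C1q library in blue. Lines are the interquartile range of members and filled points are lists called apart from matched random lists; the epithelial medians are −3.92 and −3.84 and the mesenchymal medians 1.06 and 1.56.

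The second comparison asked the same of IL-4/C1q. The same kinds of miRNA differed as after the inflammatory mixture. miR-451-5p was 283-fold lower (189 to 447) and miR-200c-3p 280.1-fold lower (204 to 396) than in the untreated library. miR-143-3p was 4.04-fold higher (4.01 to 4.07), and miR-540-3p, the highest ratio among miRNAs with at least 200 counts, 4.95-fold higher (3.92 to 6.32). Of 486 miRNAs with at least 50 counts, 177 passed the size rule, 62 higher and 115 lower, 25 of the lower ones bovine-named. Scaling by DESeq2 size factors gave 83 higher and 98 lower, and the authors' constants 82 higher and 98 lower. The split was 12 and 72 at a 4-fold minimum and 36 and 92 with the assumed dispersion. In rat-named rows alone 107 passed, 54 higher.

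The epithelial list again had 8 of 10 members lower and none higher, with a median log2 ratio of −3.84 at percentile 0. miR-200b-3p was 206-fold lower (148 to 294) and miR-205 25.8-fold lower (21.4 to 31.5). miR-203a-3p had a log2 ratio of −1.93. Against the floor, hsa-miR-934 was at least 86.4-fold lower, cja-miR-429 at least 75.8-fold and miR-141-3p at least 67.2-fold. In the erythrocyte and serum list 5 of 9 members were lower, with a median of −2.42 at percentile 0. miR-122-5p was 5.81-fold lower (5.69 to 5.94) and miR-144-5p 18.1-fold (10.7 to 32.8). The bovine-named set had 21 of 24 members lower, with a median 6.56-fold. The primate-named set had 6 of 10 lower and 0 higher, with a median 6.32-fold lower. ssc-mir-1285-p5 and cpo-miR-6529-5p, with pig and guinea pig prefixes, had log2 ratios of −4.56 and −3.52. miR-375-3p, an endocrine and epithelial miRNA in none of the lists, was 11.4-fold lower (9.44 to 13.9).

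The mesenchymal list had 6 of 9 members higher and 2 lower after IL-4/C1q, with a median of 1.56 above every random list. miR-199a-5p and miR-145-3p had log2 ratios of 1.98 and 1.70, and miR-199a-3p was 3.45-fold higher (3.41 to 3.504). miR-143-5p, which is in the astrocyte list and not in this one, had 2.22. miR-10a-5p and miR-10b-5p were lower, with log2 ratios of −3.30 and −2.77. The Dlk1-Dio3 list had 20 of 42 members higher and 1 lower, miR-369-3p, with a median of 1.03, also above every random list. miR-381-3p was 3.33-fold higher (3.097 to 3.57), miR-134-5p 3.17-fold (2.86 to 3.52) and miR-127-3p 2.71-fold (2.596 to 2.82), and miR-300-3p had a log2 ratio of 1.62. The miR-17-92 list had 3 of 15 members higher, miR-18a-5p, miR-20a-5p and miR-93-5p, with a median of 0.35 at percentile 98.2. miR-17-5p had a log2 ratio of 0.99 and passed the 2-fold limit with TMM factors (1.11), DESeq2 size factors (1.17) and totals without the most abundant miRNA (1.06).

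The IL-4 or alternative activation list did not stand apart after IL-4/C1q, with 1 of 12 members lower, none higher and a median of −0.27 at percentile 34.2. In the NF-kB list 1 of 15 members was higher and 3 were lower, with a median of −0.23 at percentile 38.2. The lower ones included miR-146a-5p, 2.35-fold (2.21 to 2.51), and miR-147, 5.28-fold (3.36 to 8.62). miR-155-5p had a ratio of 1.30 (1.23 to 1.38).

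**Figure D2:**
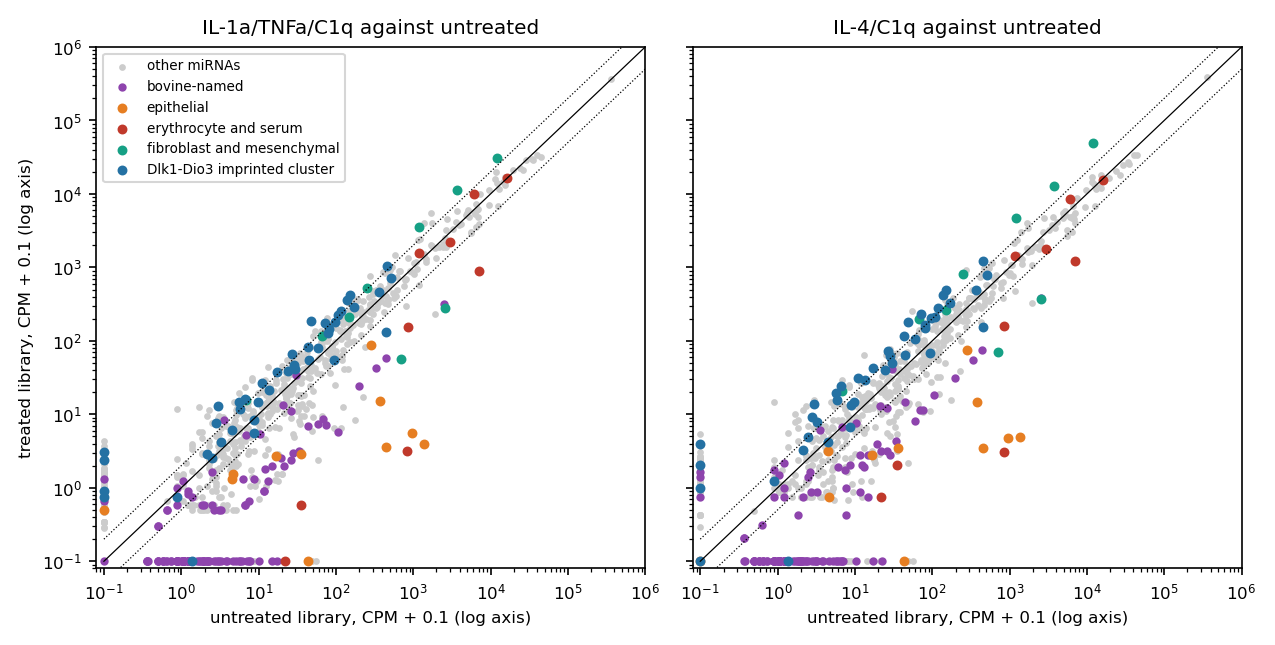
CPM in each treated library (y axis, log scale, 0.1 added) against the untreated library (x axis, log scale, 0.1 added), each point an miRNA. The solid line marks equal shares and the dotted lines 2-fold differences; most orange epithelial, some of the red erythrocyte and serum, and most of the purple bovine-named miRNAs lie below the lines, and many teal mesenchymal and blue Dlk1-Dio3 miRNAs above.

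Astrocyte-enriched miRNAs did not stand apart in either comparison with the untreated library. Their median log2 ratios were −0.20 after IL-1α/TNF-α/C1q (percentile 5.1) and −0.28 after IL-4/C1q (8.63). In both, 2 of 14 members were higher, miR-143-3p and miR-143-5p; 1 and 2 were lower, miR-449a-5p in both. The neuron-enriched list had medians of −0.45 (percentile 8.76) and −0.56 (8.4), with miR-124-3p 3.91-fold (3.41 to 4.504) and 3.56-fold (3.04 to 4.18) lower. The oligodendrocyte list had medians of −0.13 (57.5) and −0.63 (27.8), the muscle list −1.62 (8.75) and −1.39 (12.3), and the microglia and leukocyte list −0.90 (15.7) and −0.33 (55.7). The let-7 family stood at 0.02 (50.4) and −0.01 (61.4), the miR-23-27-24 clusters at −0.08 (54.7) and −0.04 (72.9), and the miR-29 family at −0.41 (46.9) and −1.04 (17.8). The miR-30 family stood at −0.22 (21.9) and −0.32 (23.8), the miR-181 family at −0.26 (25.03) and −0.40 (19.8), and the miR-34 and miR-449 family at −0.40 (15.5) and −0.35 (24). The list of miR-221 and miR-222 had medians of 0.66 (92.8) and 0.37 (85.7), the hypoxia and ischemia list 0.10 (70.3) and 0.09 (76.8), and the leukocyte adhesion and chemokine signalling list −0.29 (11.5) and −0.24 (31). The endothelial list had 2 measured members, too few for a percentile. Of the 21 lists tested in each comparison, 6 stood apart after IL-1α/TNF-α/C1q and 5 after IL-4/C1q. If list members varied independently of each other, 1.05 would by chance. Some lists hold miRNAs of a shared cluster, which may move together. The chance number for such lists may be higher and was not computed.

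The miRNAs past the size rule overlapped between the treatments. Among 486 miRNAs tested in both, 49 were higher in both treated libraries and 105 lower in both, and 0 went in opposite directions. Independent sets of these sizes would share 8.04 and 25.8. Simulated libraries with no effect, set against the shared untreated library, shared 0.03 and 0 on average. Those libraries varied by counting error alone, so values near 0 follow from how they were made and leave out variation between cultures. The control is 1 library and could not be split. Any way in which that library differed from both others would appear in both comparisons, so part or all of the excess may come from it.

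The third comparison set IL-4/C1q against the inflammatory mixture directly. Few miRNAs differed: 11 of 467 miRNAs passed the size rule, 6 higher and 5 lower with IL-4/C1q. The largest difference was mmu-miR-223-3p, a myeloid miRNA, 13.5-fold higher with IL-4/C1q (9.08 to 20.7), at 238 against 28 counts. cpo-miR-142-5p, a blood cell miRNA, was 4.87-fold higher (3.77 to 6.35), at 246 against 80. In the untreated library these had 368 and 725 counts, so mmu-miR-223-3p was 25.6-fold lower after IL-1α/TNF-α/C1q (17.4 to 39.1) and 1.90-fold lower after IL-4/C1q (1.61 to 2.25). A variant row of hsa-miR-1246 with a substitution had a log2 ratio of 1.16.

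Chosen after their values were seen, the other higher miRNAs were bta-mir-2887-1-p5 (log2 ratio 1.68), miR-217-5p (1.22) and a substituted bta-miR-146a row (1.10). The lower ones were miR-147 (−1.11), miR-501-5p (−1.13), ssc-mir-1285-p5 (−1.49), hsa-miR-7977 (−1.66) and a substituted miR-466b-5p row (−1.87), each with at most 82 counts in the higher library. In rat-named rows alone 4 miRNAs passed, and with an assumed dispersion of 0.1 also 4.

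The microglia and leukocyte list had 2 of 9 members higher with IL-4/C1q, the miR-223 and miR-142 rows, and a median log2 ratio of 0.57 at percentile 99.9. That median was the value of miR-511-3p, named after its values were seen, at 15 against 12 counts. Only 5 of the 9 members had at least 50 counts in the higher library, so the median rests on few counts. The call held with a pseudocount of 10 CPM and with a background of at least 100 counts. miR-342-3p of that list had a log2 ratio of −0.13 and miR-150-5p 0.49 (−0.12 to 1.09). miR-342-5p, named after its values were seen, had −0.66 (−1.30 to −0.05). The bovine-named set had a median of 0.50. Mesenchymal miRNAs had a median of 0.40 with 0 of 9 past the rule, and miR-143-3p was 1.60-fold higher (1.597 to 1.61). Dlk1-Dio3 miRNAs had a median of 0.22 with 0 of 42 past the rule. Both medians lay above every random list. The miR-17-92 list had a median of −0.26 at percentile 0.03 with 0 of 15 past the rule. The NF-kB list had a median of −0.25 at percentile 0.59, with miR-147 lower, and was not apart with a pseudocount of 10 CPM (percentile 2.78). The other lists lay between percentiles 6.25 and 95.5, the IL-4 list at 87.5 and the astrocyte list at 95.5.

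**Figure D3:**
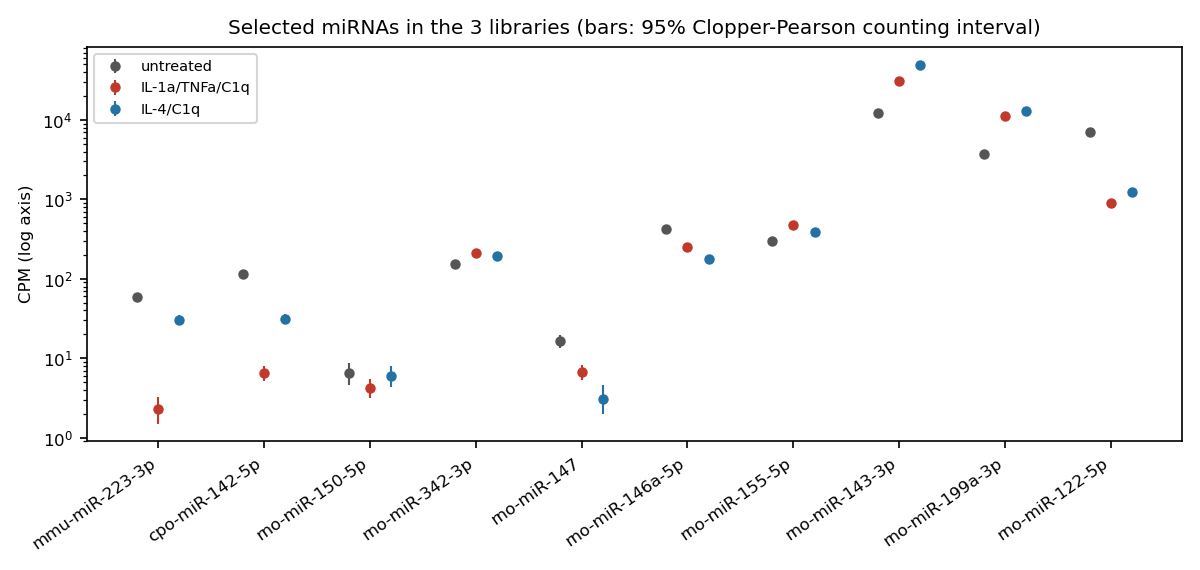
CPM (y axis, log scale) of selected miRNAs in the untreated (grey), IL-1α/TNF-α/C1q (red) and IL-4/C1q (blue) libraries, with Clopper-Pearson 95% counting intervals, often smaller than the points. mmu-miR-223-3p and cpo-miR-142-5p are lowest in the IL-1α/TNF-α/C1q library, while miR-143-3p is highest in the IL-4/C1q library, at 4.90% of its counts.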

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

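All tests in this part were chosen after the results were seen, and 7 of the 8 were changed after a first outcome. The serum test for miR-122 and its companions first used the whole range of bovine-named ratios, in which 8 of 8 ratios lay; because that range reached above 0 it was narrowed to abundant bovine-named miRNAs. The test for another RNA source first used the spread of log2 ratios among 5 abundant epithelial miRNAs, 6.20, with no rule to decide it. The test for leukocyte RNA first read the value below as excluding that source, and its rule was then made stricter. The test for RNA of another species first used miR-429 alone, 100% outside the rat-named row, and was read as in favour; it was then widened to all members with rows of both kinds. Serum RNA was first read as excluded for the miR-200 and miR-451 part, with 12 of 12 ratios below a bovine-named value that was itself a floor for a count of 0, and for the third pattern against the bovine-named upper quartile of 0.66 alone; both rules were then made stricter. The scaling test first used the lowest list median under other scalings, 0.835, which those scalings could only raise, and was replaced.

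Predicted candidates were outside the comparisons, and 4 of their ratios to the untreated library exceeded the size rule upward. After IL-1α/TNF-α/C1q, PC-3p-5687_102 was 8.12-fold higher, at 95 against 6 counts, and PC-5p-1493_789 2.03-fold higher, at 516 against 130. After IL-4/C1q, PC-3p-1507_774 was 2.10-fold higher, at 297 against 115, and PC-5p-1143_1241 2.0005-fold higher, at 532 against 216. Of 352 candidates, 14 and 13 had the 50 counts that the size rule asks for, and in each comparison 2 of these were higher and 7 lower.

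The first pattern is the excess of the miR-200 family, miR-141-3p, miR-429, miR-451-5p, miR-122-5p, miR-10a-5p, miR-10b-5p and miR-486 in the untreated library. Bovine serum RNA cannot be told apart from other causes: in the miR-200 and miR-451 part 12 of 12 ratios, upper counting bound included, lay below those of 7 abundant bovine-named miRNAs, but 3 of 24 bovine-named miRNAs, with at most 140 untreated counts, were at 0 in both treated libraries, so how far they fell has no limit, and for miR-122, miR-10 and miR-486 5 of 8 ratios lay inside the range of those 7. RNA of another source, such as epithelial cells, is a candidate explanation: 4 of 4 further epithelial miRNAs (miR-203a-3p, miR-205, miR-182 and miR-183-5p) were lower in both treated libraries, but their values were known beforehand and a treatment that lowers epithelial miRNAs would give the same. Whether that RNA came from a species other than rat stays open. Of 2 members with rows of both kinds, 1 had most untreated counts outside the rat-named row. That was miR-429, with 100% of 338 counts, against 1.80% of the miR-200b-3p counts. Sequences were not compared between species, and reads of a sequence that species share may carry the rat name. The miR-200b-3p share therefore does not speak against another species. An effect of the treatments themselves stays open and untested, since 1 untreated library cannot separate condition from library.

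The second pattern is the higher share of mesenchymal and Dlk1-Dio3 miRNAs in both treated libraries. Had foreign RNA without astrocyte-list miRNAs only diluted the untreated library, the astrocyte list would be as much higher in the treated ones. Without miR-143 it lay at least 1.01 (log2) below the mesenchymal and Dlk1-Dio3 lists, more than its interquartile range of up to 0.444. Foreign RNA that itself carried astrocyte-list miRNAs could leave such a gap, so dilution by it stays open. Those lists were flagged because they were high, so a gap was known beforehand. Scaling by 1 factor per library moves all miRNAs alike, so the same gap of 1.01 argues against such a factor as the whole cause. The gap says nothing on scaling that differs between miRNAs, which was not tested. A different mix of cells or of released vesicles between cultures and an effect of the treatments both stay open and were not tested.

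The third pattern is miR-223-3p and miR-142-5p, higher with IL-4/C1q than with IL-1α/TNF-α/C1q. Serum RNA cannot be told apart from other causes: the lower counting bound of the smaller log2 ratio, 1.92, lay above the highest bovine-named ratio, 1.73 for bta-miR-432 at 21 against 10 counts, but bta-mir-2887-1-p5 was itself higher past the size rule, at 1.68 with an upper bound of 2.12. More microglia or leukocyte RNA in the IL-4/C1q library cannot be told apart from other causes: the other 3 list members with enough counts had upper bounds of at most 1.09, below 1.92, but they are too few, and miR-342-3p is abundant enough to hide a small share. The untreated library held more of both miRNAs than either treated library, and an effect of the treatments stays open and untested.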

How the results depend on the processing

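The authors' constants, predicted candidates included, rat-named rows and removed lists were tried after the data were seen; the other settings were planned. No paired analysis was possible because each condition had 1 library, and leaving out replicates or regrouping samples was not possible for the same reason. Depth limits miRNAs with few counts, and counting intervals leave out variation between cultures. For IL-1α/TNF-α/C1q against untreated, the 177 miRNAs became 332 with at least 10 counts, 436 with no minimum, 102 with at least 200, 280 at 1.5-fold, 83 at 4-fold and 100 in rat-named rows. For IL-4/C1q against untreated, 177 became 319, 433, 99 and, at 4-fold, 84, and 107 in rat-named rows. For IL-4/C1q against IL-1α/TNF-α/C1q, 11 became 56, 90 and 3 with those count minimums, 41 at 1.5-fold, 2 at 4-fold, 4 in rat-named rows and 4 with an assumed dispersion of 0.1. Fewer or more miRNAs tested, or a looser or stricter limit, account by construction for all of these but the last. There the exact test with an assumed dispersion replaced the counting interval. Under TMM factors, DESeq2 size factors and the authors' constants the counts were 184, 190 and 189, then 178, 181 and 180, then 11 each. The highest row per name gave 173, 172 and 11, and predicted candidates included 186, 186 and 11. Without bovine-named rows and the epithelial and the erythrocyte and serum lists, 136, 137 and 9 passed. The dispersion of 0.1 left 127 and 128 against untreated.

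The overlap of 154 became 74 at 4-fold and 160 with TMM factors. Without miR-21-5p in the total, the shares of miR-9a-5p, miR-125b-5p and miR-143-3p became 6.95%, 5.40% and 8.0001%, by construction. Of 279 log2 ratios of named miRNAs, 0 reversed, 4 lost the size rule under some scaling or row choice (miR-129-5p, miR-338-3p and miR-219a-1-3p in both comparisons) and 3 gained it. Under a pseudocount of 10, a background of at least 100 counts, 5 bins and TMM factors, list calls were lost only for the IL-4 list after IL-1α/TNF-α/C1q and for the NF-kB list between the treated libraries, at the percentiles given with those results; the cause was not tested.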

Other observations

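Other miRNA groups moved little or in part. miR-133a-3p and miR-206-3p, muscle miRNAs, had log2 ratios to untreated of −1.82 and −1.69 after IL-1α/TNF-α/C1q and −1.45 and −1.88 after IL-4/C1q, all past the size rule, while miR-1-3p had −0.47 and −0.05 and was not. Among oligodendrocyte miRNAs, miR-219a-1-3p was lower in both treated libraries (−1.08 and −1.12) and miR-338-3p after IL-4/C1q (−1.03), 3 calls that other scalings ended. miR-126a-3p, an endothelial miRNA, had −1.29 after IL-1α/TNF-α/C1q and −0.55 after IL-4/C1q; the difference between the treated libraries was 0.74 and did not reach 2-fold. These were chosen after their values were seen.

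The untreated library had the fewest counts but the most rows above 0, 1244 of 1480 against 962 and 860. Its predicted candidates held 662 CPM of all rows, against 364 and 345.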
